A study of Homo sapiens with 3 samples.

How the data were processed

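Polyadenylated RNA of Hep3B cells was sequenced in 3 conditions with 1 library each: 20% oxygen, 1% oxygen, and 1% oxygen with sodium oxamate. Per the labels' protocols, 3 µg of RNA per sample was selected with oligo-dT beads, fragmented and primed with random hexamers. The protocols do not say whether the kit marks strand. Each deposited table lists the same 61533 genes with their coordinates, summed exon length and 1 value per gene, which the authors gave in FPKM (fragments scaled to exon length and library size), per the file headers. The submitters' processing notes name HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, edgeR 3.22.5 and hg38, with no role or order, and other settings are not given in the sources used here. The gene type column of the tables holds 1 value for every gene, so types were taken from GENCODE 29 by gene identifier, which matched 58356 of the 61533 genes.

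The deposited FPKM of a gene multiplied by its length was a whole multiple of a constant in each library: 100% of values above 0 lay within 0.01 of a whole number. These whole numbers were used as fragments per gene. The design had assumed deposited counts, and the recovered fragments took their place. The libraries summed to 27412147, 26309340 and 24826365 fragments. The scaling that the FPKM values imply differed between libraries by factors of 0.938, 1.06 and 1.02 relative to these sums, close to the factors used here.

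Genes with at least 10 fragments over the 3 libraries (21987, of which 14327 are protein-coding) were scaled by the trimmed mean of M values, written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, trimming 30% of log ratios and 5% of mean levels. The factors were 0.943, 1.05 and 1.01 for normoxia, hypoxia and oxamate. Levels are given in CPM, fragments scaled to the normalised library total. With 1 library per condition there is no test across samples and no p-value. A gene was counted as higher or lower by a rule of size alone: a ratio of at least 2 with at least 50 fragments in the library where it was higher. Each ratio has a 95% exact conditional binomial (Clopper-Pearson) interval. Fragments without molecular identifiers are not independent molecules, so intervals and floors cover counting error only and not differences between cultures. A gene with 0 fragments in a library was set to a floor of 3, which corresponds to 0.116, 0.108 and 0.120 CPM. Its fold is printed as the lower limit of its interval.

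Before the data were examined, 35 gene lists were written (675 entries, of which 674 matched the tables), including 4 lists of markers of other cell types, together with the comparisons, the size rule, the alternatives and the rule for naming genes. The medians of lists use a prior count of 0.5 and members with at least 50 fragments in either library. Each list with at least 5 such members was placed among 10000 random lists of the same size drawn from protein-coding genes in 20 bins of mean expression, and was said to stand apart below percentile 2.5 or above 97.5. This describes these libraries and is not a test across samples. Genes were named by rule. The rule took, per comparison, the 12 protein-coding genes each way with at least 100 fragments in the higher library, ranked by the interval bound nearest to no difference. It also took SCARB1, LDHA, LDHB, cholesterol uptake genes, and up to 4 members of each other list, the 2 with the highest and the 2 with the lowest ratio, and not every gene it took is printed. Lists share some members, and the lists and comparisons are not independent of one another.

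Both steps share the hypoxia library. Counts of genes that went in opposite directions are therefore given beside 100 simulated pairs of unchanged libraries, drawn with counting error alone or with assumed coefficients of variation of 0.1 and 0.2 between libraries, beside independent lists, and beside 100 random splits of the hypoxia fragments. With the assumed value of 0.2, an average of 160 unchanged genes were at least 2-fold higher and 170 lower, and 95% of protein-coding genes lay within 0.85 of 0 on the log2 scale. The true spread between cultures is not known here.

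The procedure was tested on simulated data drawn from the levels of the hypoxia library with counting error alone. The changed genes were protein-coding with at least 100 fragments in hypoxia, so 3-fold changes were nearly sure to pass the rule. No spread between cultures was simulated, so these data do not show how often unchanged genes would pass in separate cultures. For hypoxia against normoxia, 50 of 50 genes raised 3-fold and 50 of 50 lowered to 0.333-fold passed the rule, as did 0 of 50 raised 1.5-fold and 1 of 13195 unchanged genes, and 95.2% of the intervals of unchanged genes held the true ratio, as did 88.0% of those of the 50 genes raised 3-fold and 92.0% of those lowered to 0.333-fold. For oxamate against normoxia these were 95.2%, 90.0% and 100%. The share of exon bases that a gene shares with any other gene was computed from GENCODE 29, and genes with a large share or a near-identical copy are called uncertain, since the counting of shared fragments is not given in the sources used here. Antisense genes cannot be told from their partners where the counting does not use strand.

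Alternatives fixed beforehand were scaling by total fragments, by medians of ratios, or by totals without mitochondrial and the 10 most abundant genes; no filter on low counts; protein-coding genes only; count minimums of 10 and 200; the deposited FPKM with a pseudocount of 0.1 on the log2 scale; removal of the trend with gene length (lowess, span 0.3); the whole interval past 2-fold; random lists matched on length; and a prior count of 5. Removal of the trend with GC content, known for 99.1% of genes with at least 50 fragments, and leaving out genes that share over 20% of their exon bases were added after the data were seen. Figures were drawn with matplotlib 3.10.9.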

Results

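RNA sequencing of polyadenylated transcripts was analysed from Hep3B cells, an established human hepatoma line, in 3 conditions: 20% oxygen (normoxia), 1% oxygen (hypoxia), and 1% oxygen with sodium oxamate, an inhibitor of lactate dehydrogenase, the enzyme that converts pyruvate to lactate. There was 1 library per condition, so no difference below has a replicate check and no p-value across samples is given. The design text gives 48 hours for the culture with oxamate and no separate time for the other conditions. The libraries held 27412147 (normoxia), 26309340 (hypoxia) and 24826365 (oxamate) fragments assigned to genes, and 24566, 27462 and 27505 genes had at least 1 fragment. Ratios are of normalised fragment counts, with 95% exact conditional binomial intervals that cover counting error only. A gene was counted as higher or lower when the ratio was at least 2-fold and the library with the higher value held at least 50 fragments.

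The first comparison asks how low oxygen alters gene expression in these cells, and in particular the cholesterol uptake receptor that the series title names. SCARB1, which encodes the scavenger receptor that takes up cholesteryl esters from high-density lipoprotein, was 2.5-fold higher in hypoxia (interval 2.41 to 2.59). LDHA, which encodes a subunit of lactate dehydrogenase, was 3.48-fold higher (3.41 to 3.55). Targets of the hypoxia-inducible factors (HIF) were higher, with 30 of 41 measured members at least 2-fold higher and 0 lower, while 17 of 23 cholesterol synthesis genes were at least 2-fold lower and 0 higher. Hepatocyte genes, mitochondrially encoded transcripts and genes of ribosome biogenesis were lower as groups. In all, 1468 genes were higher and 1093 lower among 13549 with enough fragments.

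SCARB1 (ENSG00000073060_17) lies on the minus strand of chromosome 12 from 124776856 to 124882668 (hg38), and its exons overlap no other annotated gene. It had 4075 fragments in normoxia, or 158 CPM (interval 153 to 163), 10910 in hypoxia, or 394 CPM (387 to 402), and 5698 with oxamate, or 228 CPM (222 to 234). The deposited FPKM values were 10.6, 26.4 and 15.1. The list of 12 cholesterol uptake genes as a whole did not stand apart in hypoxia: 3 members were higher, 2 lower and 7 neither, with a median log2 ratio of 0.17, at percentile 94.14 of 10000 random lists matched on expression. Besides SCARB1, the members that were higher were VLDLR, the very-low-density lipoprotein receptor, at 2.23-fold (1.95 to 2.56), and the fatty acid and lipoprotein receptor CD36 at 2.09-fold (1.65 to 2.67). VLDLR and CD36 both fell below the 2-fold rule without the gene length trend (log2 0.82 and 0.83) and when the whole interval had to pass it, and CD36 also with FPKM (0.88) and without the GC trend (0.84). LRP8 was 2.64-fold lower (2.20 to 3.18), and the endocytic receptor gene LRP1 was 1.91-fold higher (1.87 to 1.96), which passed the 2-fold rule under scaling by total fragments (log2 1.09) and 2 other settings. Further members stood at 1.81-fold lower for NPC1L1, 1.48-fold lower for LRPAP1, 1.51-fold higher for MYLIP and 1.07-fold lower for PDZK1.

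**Figure D1:**
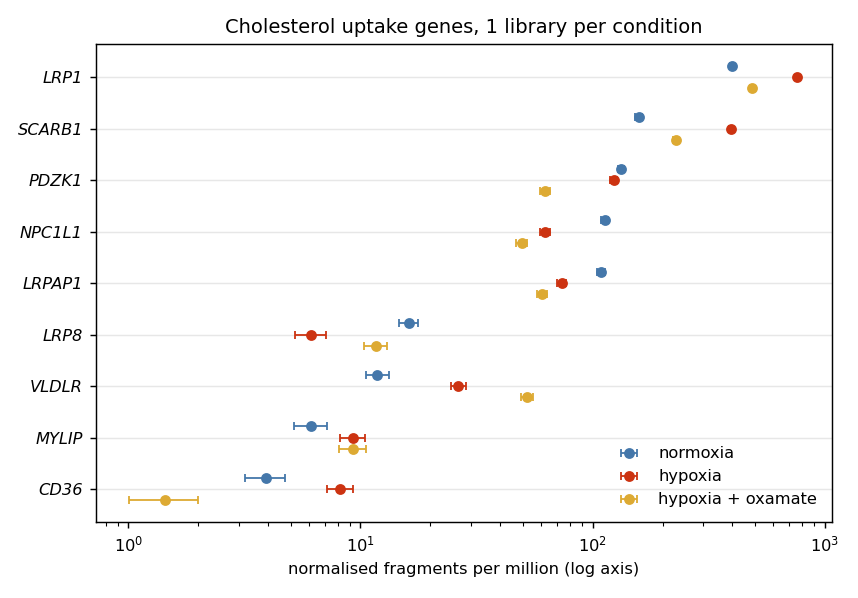
CPM (normalised fragments, log axis) of 9 cholesterol uptake genes in normoxia, hypoxia and hypoxia with oxamate, 1 library each; points are the values and bars are 95% Poisson intervals, which cover counting error only. SCARB1 stood at 158, 394 and 228 CPM, and CD36 at 3.91, 8.17 and 1.44.

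The HIF target list had a median log2 ratio of 1.60 in hypoxia, above all 10000 matched random lists. ANGPTL4, an inhibitor of lipoprotein lipase, was 45.2-fold higher (32.4 to 65.1). The glucose transporter gene SLC2A3, with 0 fragments in normoxia and 109 in hypoxia, was at least 27.2-fold higher by the lower limit of its interval. The value of SLC2A3 is uncertain, because its close paralog SLC2A14 had 72, 566 and 105 fragments in the 3 libraries and the division of fragments between them is not known. The lowest members were CA12, 1.73-fold lower (1.61 to 1.86), and JMJD6, 1.16-fold lower (1.08 to 1.25). Of 14 glycolysis genes, 7 were higher and 0 lower, with a median of 1.08, also above all random lists. The enolase gene ENO2 was 11-fold higher (9.29 to 13.2), while PGAM1 and GPI stood at 1.26-fold higher and 1.08-fold lower. Genes of lactate and pyruvate handling went both ways, with 5 of 14 higher, 3 lower and a median of -0.37 (percentile 11.96), and without genes that share exons the median was 0.51, above the random range. Among them the pyruvate dehydrogenase kinase genes PDK1 and PDK4 were 9.97-fold (8.78 to 11.4) and 7.29-fold (4.79 to 11.5) higher, and MPC1, a subunit of the mitochondrial pyruvate carrier, was 3.71-fold lower (3.36 to 4.09). LDHB, which encodes the other main subunit of lactate dehydrogenase, had 0 fragments in normoxia, 0 in hypoxia and 7 with oxamate, so no ratio is given for it, and 33.4% of its exon bases overlap another gene, which makes these values uncertain. Of 21 writers and erasers of lactylation and acylation, 0 were higher and 3 lower, with a median of -0.15 (percentile 61.595). The acetyl-CoA synthetase gene ACSS2 was 2.76-fold lower (2.53 to 3.01) and SUCLG1, for a subunit of succinyl-CoA ligase, 2.64-fold lower (2.47 to 2.81).

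Cholesterol synthesis genes had a median log2 ratio of -1.38 in hypoxia, below all 10000 random lists. HMGCS1, which encodes the synthase that makes the substrate of HMG-CoA reductase, was 4.28-fold lower (4.14 to 4.43), and ACAT2 was 3.53-fold lower (3.39 to 3.68), although 52.3% of the exon bases of ACAT2 overlap another gene, which makes its value uncertain. PMVK stood at 1.03-fold higher and STARD4, for a sterol carrier, at 1.09-fold lower. Genes of fatty acid synthesis and desaturation had 4 of 16 members lower and 0 higher, with a median of -0.72 (percentile 0.01). GPAM, the mitochondrial acyltransferase of the first step of glycerolipid synthesis, was 23.5-fold lower (18.4 to 30.5), while SREBF1 stood at 1.04-fold higher. Genes of cholesterol efflux, transport and esterification (1 of 14 higher, 2 lower, median -0.41, percentile 8.17) and of fatty acid oxidation (1 of 18 higher, 1 lower, median -0.10, percentile 70.38) lay within the range of random lists. In the former, APOA1, the main protein of high-density lipoprotein, was 3.20-fold lower (3.08 to 3.34).

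All genes on the mitochondrial chromosome together took 8.46% of the fragments in normoxia, 5.80% in hypoxia and 7.21% with oxamate. Of the 13 genes on the list of mitochondrially encoded genes, 6 were lower in hypoxia and 0 higher. Their median was -0.997, below all random lists. MT-ND2 was 2.98-fold lower (2.95 to 3.01), whereas MT-ND5 was 1.04-fold lower and MT-ND6 1.14-fold higher. Nuclear genes of oxidative phosphorylation were lower by smaller amounts, with 3 of 31 lower, 1 higher and 27 neither, and a median of -0.66 below all random lists. ATP5MC1, for a subunit of ATP synthase, was 3.32-fold lower (2.98 to 3.70). The genes of the tricarboxylic acid cycle had a median of -0.57 (percentile 0.35; 4 of 18 lower and 0 higher), with IDH1 3.35-fold lower (3.2 to 3.5) and IDH2 1.85-fold higher (1.80 to 1.90).

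Hepatocyte secretory and identity genes had a median of -0.73, below all random lists, with 10 of 26 lower, 1 higher and 15 neither. APOH, a plasma apolipoprotein gene, was 9.89-fold lower (9.31 to 10.5), and TTR, which encodes transthyretin, was 5.13-fold lower (4.49 to 5.89). The member past the rule in the other direction was TF, the transferrin gene, which was 3.38-fold higher (3.35 to 3.42). Fetal liver and liver cancer genes lay within the random range (2 of 14 higher, 1 lower, median -0.33, percentile 14.61), as did genes of bile acid and drug metabolism (0 of 9 higher, 3 lower, median -0.39, percentile 18.855). IGF2 was 3.38-fold higher (3.27 to 3.49), with 75.0% of its exon bases shared with another annotated gene. The levels of markers of other cell types are given with these groups as measured facts. LYZ, the most abundant of 12 blood cell markers, had 37.3, 31.8 and 60.0 CPM in normoxia, hypoxia and oxamate, and 34.0% of its exon bases overlap another gene. The endothelial marker PECAM1 had 1.28, 8.32 and 20.0 CPM, and the other 9 endothelial markers lay below 1 in every library. Of 5 measured stellate cell and fibroblast markers, 0 were higher and 0 lower in hypoxia (median 0.38, percentile 84.465). Of 4 measured markers of cholangiocytes and other epithelia, 2 were lower and 0 higher, and KRT19 was 1.67-fold lower (1.62 to 1.72).

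Genes of ribosome biogenesis and MYC targets had 14 of 21 members lower in hypoxia and 0 higher, with a median of -1.12 below all random lists, and MYC was 4.42-fold lower (4.12 to 4.75). The exception in direction was TFRC, the transferrin receptor gene, at 1.53-fold higher (1.49 to 1.57). Targets of ATF4, a transcription factor of amino acid stress, had 11 of 22 lower and 3 higher (median -0.98, below all random lists). SLC7A5, an amino acid transporter gene, was 4.91-fold lower (4.65 to 5.19) and the serine synthesis gene PHGDH 4.63-fold lower (4.36 to 4.93), whereas GDF15 was 4.45-fold higher (4.29 to 4.63). Targets of NRF2, a regulator of antioxidant genes, had 8 of 15 lower and 0 higher (median -1.05, below all random lists), with the ferritin light chain gene FTL 4.38-fold lower (4.32 to 4.43) and NQO1 3.53-fold lower (3.27 to 3.81). Heat shock protein genes had 4 of 12 lower and 0 higher (median -0.80, percentile 0.02), and HSPD1, a mitochondrial chaperone gene, was 2.79-fold lower (2.73 to 2.85). S phase and DNA replication genes had a median of -0.58 (percentile 0.11) with only CDC6, at 2.03-fold lower (1.94 to 2.12), past the 2-fold rule among 24. Mitosis genes had 0 of 21 past the rule in either direction (median -0.41, percentile 4.24), but lay below the random range without the GC trend (median -0.55).

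Immediate early genes were higher, with 5 of 11 at least 2-fold higher, 0 lower and a median of 0.94 (percentile 99.99), including FOS at 5.80-fold (5.08 to 6.64) and JUNB at 5.20-fold (4.92 to 5.49). The list of epithelial-mesenchymal transition and extracellular matrix genes had a median of 0.57 (percentile 99.76), although only 3 of 15 were higher and 2 lower. LOXL2, which crosslinks collagen, was 83.4-fold higher (45.1 to 174) and the growth factor-like gene CCN2 2.22-fold lower (2.11 to 2.33). Replication-dependent histone genes had 3 of 7 higher and 0 lower (median 0.80, percentile 98.75), and moved inside the random range with the count minimum at 10. Such transcripts mostly lack a poly(A) tail and are poorly captured by poly(A) selection. The lists that lay within random ranges were endoplasmic reticulum chaperones and XBP1 targets (median -0.31, percentile 20.805), p53 targets (-0.12, 60.775), the interferon response (-0.39, 10.915), NF-kB and acute phase genes (0.17, 94.66), autophagy and lysosome genes (-0.30, 22.18), cytosolic ribosomal proteins (-0.36, 6.07) and iron handling (0.16, 95.39). The NF-kB list lay above the random range without the gene length trend (median 0.34) and when random lists were matched on length.

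The protein-coding genes with the largest ratios included AKAP12, a scaffold for protein kinase A, which went from 1272 to 84907 fragments and was 62.4-fold higher in hypoxia (59.0 to 66.0). LGI4 was 302-fold higher, but on 3 fragments in normoxia its interval ran from 103 to 1465. ANGPTL2 was 85.2-fold higher (60.2 to 125), the acyl-CoA synthetase gene ACSL5 60.0-fold (38.3 to 100.04), the natriuretic peptide gene NPPB 50.5-fold (30.5 to 90.7) and the insulin-like growth factor binding protein gene IGFBP1 52.8-fold (30.04 to 103). ADGRF4, with 0 fragments in normoxia, was at least 46.4-fold higher by the lower limit of its interval. At the other end, CPS1, which encodes the first enzyme of the urea cycle, was 119-fold lower (32.6 to 991, on 2 fragments in hypoxia). The steroid and bile acid sulfotransferase gene SULT2A1 was 20.6-fold lower (15.6 to 27.9), the osteopontin gene SPP1 18.2-fold lower (14.3 to 23.5), the prolactin receptor gene PRLR 12.2-fold lower (9.83 to 15.3) and PPARGC1B, a coactivator of mitochondrial genes, 18.9-fold lower (9.71 to 42.1).

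Of the genes past the rule in this comparison, 961 of the higher and 1009 of the lower were protein-coding, and the median log2 ratio of protein-coding genes was -0.16. Scaling by total fragments moved that median to -0.01 and gave 1775 higher and 750 lower genes, so that the balance of directions depends on the scaling.

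The second comparison asks how gene expression in hypoxia differs with sodium oxamate. These libraries do not measure lactate or the activity of lactate dehydrogenase. SCARB1 was 1.73-fold lower with oxamate than in hypoxia alone (1.68 to 1.79), which is below the 2-fold rule, and it remained 1.45-fold above normoxia (1.39 to 1.51). HIF targets were higher again, with 12 of 41 at least 2-fold higher and 1 lower, and ATF4 targets were higher, with 8 of 22 higher and 0 lower. Mitosis genes and hepatocyte genes were lower, with 4 of 21 and 10 of 26 past the rule. Overall in this comparison 813 genes were higher and 696 lower among 13733, and the median log2 ratio of protein-coding genes was -0.03. Scaling by total fragments gave 722 higher and 802 lower genes instead, so here too the balance of directions depends on the scaling.

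The 12 cholesterol uptake genes had 0 members higher, 1 lower and 11 neither with oxamate, with a median of -0.25 (percentile 5.38). CD36 was 5.67-fold lower (3.98 to 8.31). VLDLR was 1.98-fold higher (1.80 to 2.17) and LRP8 1.90-fold higher (1.57 to 2.32). LRP1 was 1.56-fold lower (1.53 to 1.60) and PDZK1, which encodes a scaffold that binds the SCARB1 receptor, was 1.97-fold lower (1.86 to 2.10). Further ratios were 1.21-fold lower for LRPAP1 and 1.26-fold lower for NPC1L1, and MYLIP stood at 1.00-fold. PDZK1 passed the 2-fold rule under scaling by total fragments, where its log2 ratio was -1.04, and under 2 other settings. Cholesterol synthesis genes were higher, with 4 of 23 past the rule, 0 lower and a median of 0.48 (percentile 99.99). INSIG1, a sterol-regulated inhibitor of this pathway, was 2.88-fold higher (2.65 to 3.12) and SC5D 2.18-fold higher (2.07 to 2.29), while PMVK was 1.84-fold lower (1.48 to 2.29). Genes of efflux, transport and esterification had 1 of 14 higher and 1 lower (median 0.03, percentile 59.78): the cholesterol exporter gene ABCA1 was 2.49-fold higher (2.32 to 2.67) and APOA1 2.26-fold lower (2.11 to 2.41).

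**Figure D2:**
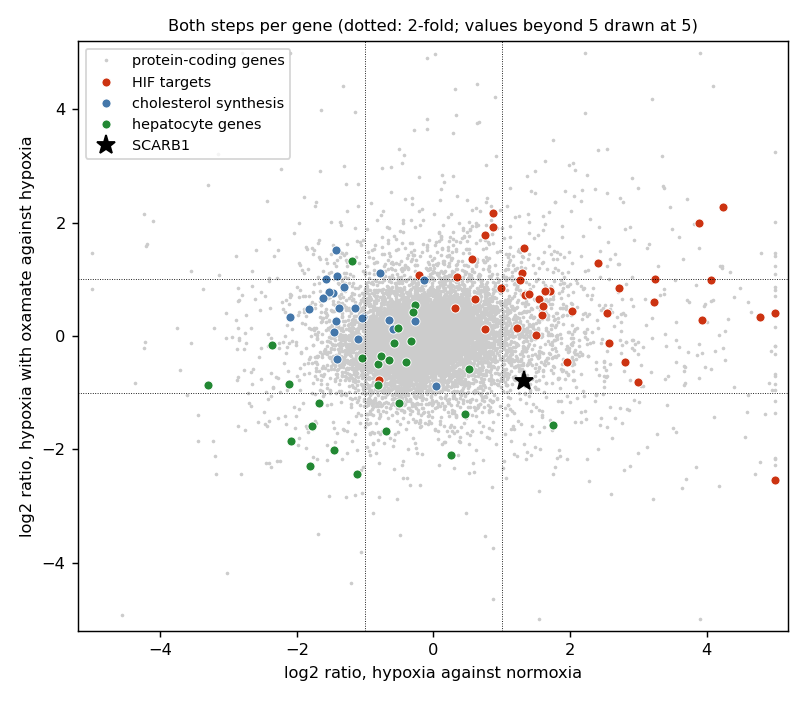
Log2 ratio of hypoxia against normoxia (horizontal) and of hypoxia with oxamate against hypoxia (vertical) for protein-coding genes with at least 50 fragments in 1 library; each point is a gene, from 1 library per condition, and values beyond 5 are drawn at 5. SCARB1 lay at 1.32 and -0.79, and the 3 coloured lists had medians of 1.60 and 0.66 (HIF targets), -1.38 and 0.48 (cholesterol synthesis) and -0.73 and -0.72 (hepatocyte genes).

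The HIF targets had a median log2 ratio of 0.66 with oxamate, above all 10000 random lists. PPFIA4 was 4.85-fold higher (4.29 to 5.49) and STC2 4.49-fold higher (4.30 to 4.69), whereas SLC2A3, uncertain as above, was 5.80-fold lower (3.46 to 10.3) and EPO, the erythropoietin gene, 1.75-fold lower (1.35 to 2.27). Glycolysis genes had 4 of 15 higher, 0 lower and a median of 0.28 (percentile 98.2), and moved inside the random range without genes that share exons (median 0.26). The phosphofructokinase gene PFKP was 9.71-fold higher (6.99 to 13.8) and ENO2 4.86-fold higher (4.61 to 5.13). LDHA was 1.15-fold higher (1.14 to 1.17). Genes of lactate and pyruvate handling had 0 of 14 higher and 2 lower (median 0.03, percentile 61.58), the latter being PDK2, 3.46-fold lower (2.71 to 4.47) with 38.6% of its exon bases overlapping another gene, and PDK4, 2.48-fold lower (1.88 to 3.31). SLC16A3, which encodes the lactate exporter MCT4, was 1.80-fold higher (1.75 to 1.85). Of the 21 lactylation writers and erasers, 2 were higher and 0 lower (median 0.04, percentile 63.155): ACSS2 at 2.43-fold (2.23 to 2.66) and the acetyltransferase gene KAT2B at 2.47-fold (2.29 to 2.65).

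ATF4 targets had a median of 0.81, above all random lists. The cystine transporter gene SLC7A11 was 3.60-fold higher (3.32 to 3.91), and STC2, also among the HIF targets, is 1 of the 2 genes the lists share. NRF2 targets had 3 of 15 higher and 1 lower (median 0.32, percentile 99.16). The malic enzyme gene ME1 was 3.89-fold higher (3.54 to 4.28) and AKR1B10 15.9-fold higher (9.59 to 28.3), while HMOX1 was 2.0-fold lower (1.84 to 2.19). NF-kB and acute phase genes had 4 of 12 higher and 1 lower (median 0.61, above all random lists), with the chemokine gene CCL20 3.20-fold higher (3.08 to 3.33), BIRC3 2.89-fold higher (2.61 to 3.21) and ORM1 5.39-fold lower (4.19 to 7.01). Mitochondrially encoded genes had a median of 0.40 (percentile 99.755) with 0 of 13 past the rule, cytosolic ribosomal proteins a median of 0.24 (percentile 99.39) with 0 of 30 past it, and immediate early genes a median of 0.49 (percentile 99.9) with 1 of 12 higher, NR4A1 at 2.49-fold (2.13 to 2.92). Histone genes had 2 of 7 higher (median 0.69, percentile 99.78), with H2BC4 at 2.90-fold (2.17 to 3.91). The NRF2 and histone lists moved inside the random range with the count minimum at 10 (medians 0.24 and 0.12), and the immediate early list with it at 200 (median 0.19).

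Mitosis genes had a median of -0.85, below all random lists, with 0 of 21 higher. CCNA2, the cyclin A2 gene, was 2.24-fold lower (2.08 to 2.42) and CCNB2 2.17-fold lower (1.98 to 2.38). S phase genes had a median of -0.37, also below all random lists, with 1 of 24 lower, the replication factor gene GINS2 at 2.19-fold (1.88 to 2.56). Hepatocyte genes had a median of -0.72, below all random lists, with 1 higher and 15 neither. CEBPA, a transcription factor of hepatocyte genes, was 5.43-fold lower (4.94 to 5.99), with 43.4% of its exon bases overlapping another gene, and the fibrinogen gene FGB was 4.91-fold lower (4.0 to 6.1). FOXA2, another hepatocyte transcription factor gene, stood at 1.46-fold higher (1.36 to 1.56). Fetal liver and liver cancer genes had 2 of 14 higher, 3 lower and a median of -0.26 (percentile 2.37), with PEG10 2.51-fold lower (2.44 to 2.58) and SOX9 2.41-fold higher (2.3 to 2.5). The fetal liver list moved inside the random range under 5 alternative settings. Iron handling genes had 4 of 14 lower and 1 higher (median -0.35, percentile 0.92). The hemojuvelin gene HJV was 7.13-fold lower (4.35 to 12.4) and TFR2 3.38-fold lower (2.26 to 5.20), and BMP6, a growth factor that induces hepcidin, was 7.05-fold higher (5.35 to 9.44). Fatty acid oxidation genes had 3 of 18 lower and 0 higher (median -0.41, percentile 0.06), including EHHADH, for a peroxisomal enzyme, at 2.77-fold (2.31 to 3.34).

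Endoplasmic reticulum chaperones and XBP1 targets had a median of -0.32 (percentile 0.14), with SDF2L1 2.89-fold lower (2.51 to 3.32), but DNAJB9 and EDEM1 were 2.39-fold (2.20 to 2.60) and 2.11-fold (2.02 to 2.20) higher. Ribosome biogenesis and MYC targets had a median of -0.28 (percentile 0.44) with 0 of 21 lower and ODC1, the ornithine decarboxylase gene, 3.53-fold higher (3.32 to 3.75). This list moved inside the random range when the random lists were matched on gene length. Other lists lay within random ranges: fatty acid synthesis and desaturation (median -0.07, percentile 31.97), nuclear oxidative phosphorylation (-0.04, 36.17), the tricarboxylic acid cycle (-0.14, 9.275), bile acid and drug metabolism (-0.23, 17.04), heat shock proteins (-0.22, 5.23), p53 targets (0.20, 95.56), the interferon response (-0.07, 44.965), epithelial-mesenchymal transition and extracellular matrix (0.23, 94.06; above the range at 0.31 with the count minimum at 200), autophagy and lysosome (0.11, 81.485) and stellate cell markers (-0.36, 24.495).

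**Figure D3:**
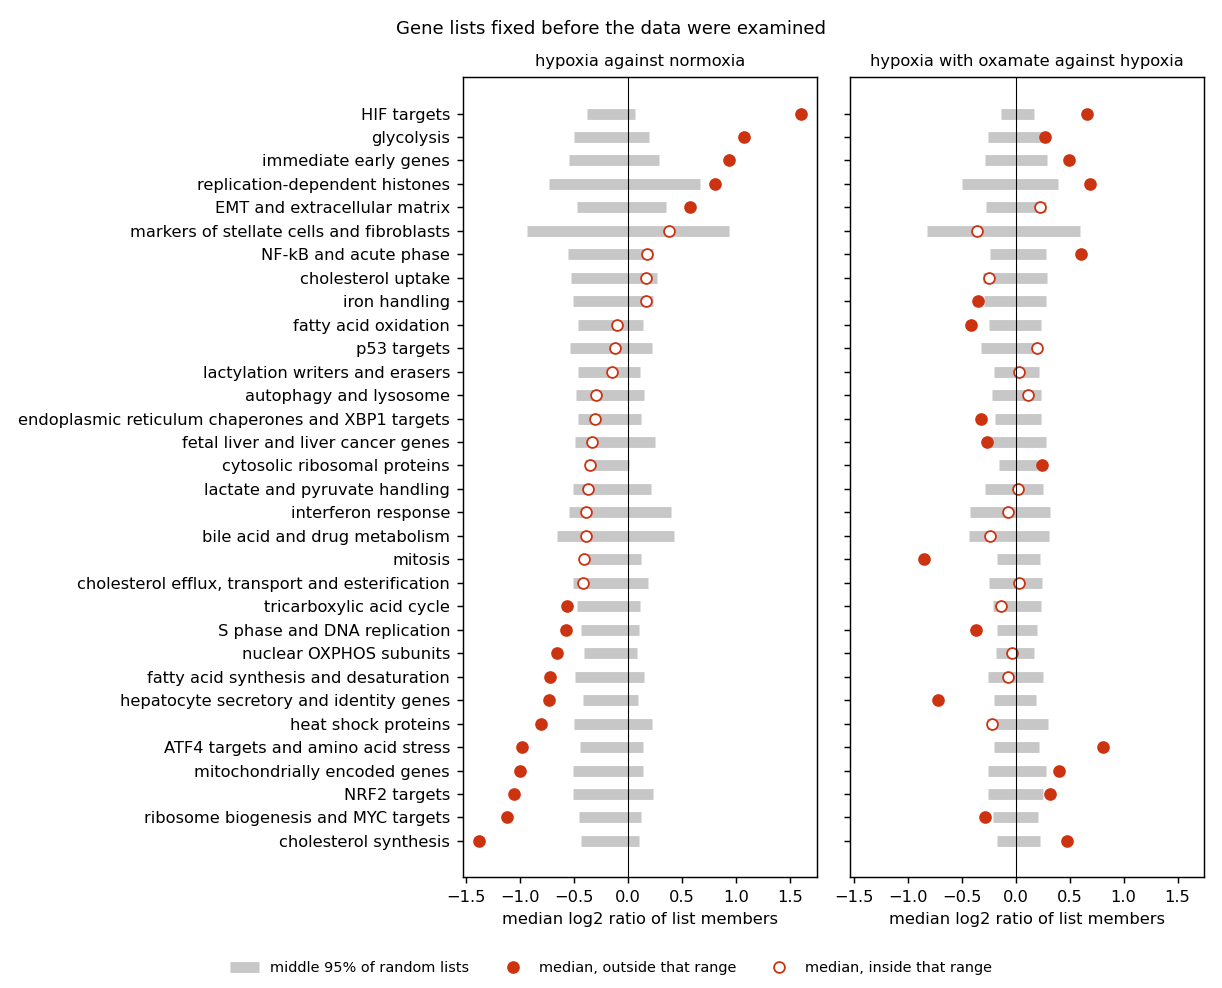
Median log2 ratio of the members of each gene list with at least 5 measured members, in hypoxia against normoxia (left) and hypoxia with oxamate against hypoxia (right), 1 library per condition; grey bars span the middle 95% of 10000 random lists matched on expression, and filled points lie outside them. HIF targets stood at 1.60 and 0.66, cholesterol synthesis at -1.38 and 0.48, ATF4 targets at -0.98 and 0.81, and mitosis at -0.41 and -0.85.

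Among single genes, PRSS35, a serine protease family member, had 12, 0 and 1228 fragments in normoxia, hypoxia and oxamate. By the lower limit of its interval it was at least 368-fold higher with oxamate than in hypoxia. AKR1B1, which encodes aldose reductase, was 74.8-fold higher (40.4 to 157) and the betaine transporter gene SLC6A12 12-fold higher (11.1 to 12.9). The endothelin receptor gene EDNRB was 31.4-fold higher (20.9 to 49.3), the calpain gene CAPN8 21.2-fold (18.8 to 24.0) and PTX3, a secreted pattern recognition protein gene, 18.1-fold (13.6 to 24.7). BOLA2B, 164-fold higher (45.1 to 1363, on 2 fragments in hypoxia), has a near-identical copy, and the urokinase gene PLAU, 21.4-fold higher (11.4 to 45.2), shares 31.1% of its exon bases with another gene, so both values are uncertain. The calcium pump gene ATP2B2 was 11.5-fold lower (9.75 to 13.6). TMPRSS6, a protease that acts on hemojuvelin, was 8.68-fold lower (7.20 to 10.6), and NKD1 and LGR5, both known targets of Wnt signalling, were 7.38-fold (6.1 to 9.0) and 4.94-fold (4.62 to 5.30) lower. SPTLC3, for a subunit of serine palmitoyltransferase, was 11.3-fold lower (5.52 to 26.9).

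Genes that went one way in hypoxia and the other with oxamate were counted across both comparisons, which share the hypoxia library. In all, 175 genes were at least 2-fold higher in hypoxia and then at least 2-fold lower with oxamate, and 90 were lower and then higher. A further 139 genes were higher in both steps and 93 lower in both. Among the 13313 genes measured in both steps, 1468 were higher and 949 lower in hypoxia, and 555 higher and 696 lower with oxamate, and independent lists of these sizes would give 76.7, 39.6, 61.2 and 49.6 genes for these 4 patterns. In simulated unchanged libraries that share the hypoxia library, 0.72 and 0.10 genes went in opposite directions with counting error alone, 3.36 and 1.09 with an assumed coefficient of variation of 0.1 between libraries, and 49.4 and 53.3 with 0.2. Splitting the hypoxia fragments at random so that each comparison used its own part gave 155 and 86.4 genes in opposite directions, and 158 and 102 in the same direction. All 4 patterns, those in the same direction included, exceeded the counts from independent lists, so the excess was not particular to opposite directions. The split removes shared counting error only. Part of the counts in opposite directions may still come from the shared library, since a library of its own for each comparison was not analysed here. The covariance of the log2 ratios over 12041 protein-coding genes was 0.0512, against -0.00828, -0.0296 and -0.0944 in the 3 simulations and 0.0580 with split fragments. With the count minimum at 10 the covariance was -0.0404, so its sign depends on genes with few fragments, and the genes in opposite directions numbered 830 and 267, against 57 and 54 with the minimum at 200. Across genes, which are not independent replicates, Pearson's r was 0.0823 and Spearman's rho 0.129. SCARB1 was not among the 175 genes because its ratio with oxamate was below 2-fold.

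The third comparison sets hypoxia with oxamate against normoxia. VLDLR was 4.41-fold higher (3.89 to 5.01), while NPC1L1, PDZK1 and CD36 were 2.28-fold (2.13 to 2.44), 2.12-fold (2.0 to 2.3) and 2.71-fold (1.84 to 4.09) lower. PDZK1 fell below the 2-fold rule here under scaling by total fragments (log2 -0.99), over protein-coding genes (-0.97) and without the gene length trend (-0.80), and CD36 with FPKM (-0.997) and the count minimum at 200, and both when the whole interval had to pass it. HIF targets were at least 2-fold higher in 36 of 40 members and lower in 1, with a median of 2.43. Hepatocyte genes were lower in 17 of 27 (median -1.43), ribosome biogenesis and MYC targets in 17 of 21 (-1.47), mitosis genes in 13 of 21 (-1.22) and S phase genes in 11 of 24 (-0.96), and each of these 4 medians lay below all random lists. In all 2091 genes were higher and 2079 lower among 13597, or 2321 and 1780 under scaling by total fragments.

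Cholesterol synthesis genes remained lower than in normoxia, with 6 of 23 past the rule, 0 higher and a median of -0.72 (percentile 0.105), with HMGCS1 3.40-fold lower (3.30 to 3.52). ATF4 targets lay within the random range (median -0.09, percentile 63.72; 6 of 22 higher, 5 lower), as did mitochondrially encoded genes (-0.53, 5.67; 2 of 13 lower). The cholesterol uptake list also lay within it (median -0.35, percentile 22.93), with 2 of 12 higher and 4 lower. LDHA was 4.01-fold higher (3.93 to 4.09) and ENO2 53.6-fold higher (45.4 to 63.7). Among single genes, CAPN8 was 362-fold higher (219 to 647), LOXL2 335-fold (182 to 699) and AKAP12 102-fold (96.7 to 108). GPAM was 713-fold lower, on 2 fragments with oxamate, with an interval from 197 to 5890.1. The acute phase genes ORM1 and ORM2, which are near-identical copies and so uncertain individually, were 38.1-fold (30.1 to 48.8) and 24.9-fold (19.6 to 32.2) lower. SCARB1 stood at a log2 ratio of 0.53, and removing the trend of the ratios with gene length reduced this to 0.18.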

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

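The removal of the GC trend and the leaving out of genes that share exons were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because each condition had 1 library, and for the same reason no library could be left out. With the count minimum at 10, the genes at least 2-fold higher and lower in hypoxia numbered 3618 and 1772, those with oxamate against hypoxia 2079 and 1866, and those higher with oxamate against normoxia 4351. With it at 200, 723 genes were higher in hypoxia, 467 higher and 337 lower with oxamate against hypoxia, and 1225 higher with oxamate against normoxia. Under the minimum of 200, genes higher in hypoxia no longer outnumbered the lower, at 847, and those lower with oxamate against normoxia, at 1680, outnumbered the higher. Genes higher in hypoxia and then lower with oxamate numbered 830 and 57 under these minimums, and those lower and then higher 267 and 54, by construction from more or fewer genes. The covariance of both steps was -0.0404 with the minimum at 10 and 0.0731 at 200, so its sign depends on genes with few fragments. Requiring the whole interval past 2-fold left 944 higher and 665 lower genes in hypoxia, 491 higher and 307 lower with oxamate against hypoxia, and 72 and 37 in opposite directions. The log2 ratio of SCARB1 in hypoxia (1.32) was 1.48 under scaling by total fragments, 1.43 by totals without abundant genes, 1.42 over protein-coding genes and 1.01 without the gene length trend. With oxamate against hypoxia (-0.79) it was -0.85 under scaling by total fragments. With oxamate against normoxia (0.53) it was 0.63, 0.59, 0.65 and 0.18 under those same 4 settings, and the cause of the shift with gene length was not tested. Other scalings and gene filters move all genes together and cannot change the place of a list, so these 475 medians are left out. Of the other 758 recomputed list medians, 728 kept their place inside or outside the random range and their sign where they lay outside. Another 18 moved inside, 12 moved outside and 0 changed sign after lying outside. The 728 include 95 with FPKM, which are the same fragments rescaled apart from the pseudocount, and 95 with the prior count of 5. Both settings could hardly move a list. Of 1291 recomputed ratios of named genes, 1261 kept their side of the 2-fold rule, 23 fell below it, 7 passed it and 0 reversed. These came from 108 pairs of gene and comparison: genes named for extreme ratios, LDHA, and cholesterol uptake genes other than SCARB1. Members of the other lists were not recomputed singly unless they were named for extreme ratios. Genes picked for extreme ratios could hardly cross the rule. The minimum of 10 could move no gene, and all 108 stayed the same under it. The counts therefore say little about how stable a named ratio is. With 24826365 to 27412147 fragments per library, genes under 50 fragments in both libraries of a comparison were not judged. The spread between cultures cannot be estimated at any depth from 1 library per condition.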

Other observations

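Of the tests below, those of an osmotic response and of other cell types were chosen after the result was seen, and the tests that remove a GC trend were added after the data were seen.

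Several classes of noncoding genes had more members past the rule upward than downward in hypoxia. Long intergenic RNA genes took 0.245% of fragments in normoxia, 0.384% in hypoxia and 0.434% with oxamate, and 104 of 314 were at least 2-fold higher in hypoxia against 20 lower, with a median log2 ratio of 0.52. Antisense genes had 136 of 455 higher and 20 lower (median 0.50), sense intronic genes 21 of 63 higher and 4 lower (median 0.71), processed pseudogenes 35 of 225 higher and 14 lower with a median on the other side of 0 (-0.11), and protein-coding genes 961 of 11847 higher and 1009 lower (median -0.16). Counting that ignores strand would give antisense genes the fragments of their partners, and the counting is not given in the sources used here. Sense intronic genes lie on the strand of their host gene, so strand would not separate them from fragments of its introns. The noncoding classes were also not matched with protein-coding genes on expression. Of all genes past the rule in hypoxia, 67.1% were higher with the count minimum at 10, and 46.1% with it at 200. Under the main setting the share was 57.3%. These shares include the noncoding genes, so they cannot separate gene type from low abundance. A pattern of genes with few fragments in general therefore stays open. With oxamate against hypoxia the medians of long intergenic, antisense and sense intronic genes were 0.13, 0.07 and 0.19, with 57 higher and 37 lower long intergenic genes.

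AKR1B1 (aldose reductase), SLC6A12 and SLC5A3, whose products supply cells with osmolytes, were higher with oxamate, and no list of such genes was fixed beforehand. AKR1B1 and SLC6A12 were named by rule for their high ratios, and SLC5A3, the myo-inositol transporter gene, was chosen after its values were seen. These genes therefore do not stand for all genes of osmolyte supply. SLC5A3 had 55.2, 94.3 and 763 CPM in normoxia, hypoxia and oxamate, and was 8.09-fold higher with oxamate than in hypoxia (7.77 to 8.43). Fragments moved between partners are argued against, since the families summed with AKR1B10 and AKR1B15, MRPS6 and SLC6A13 were higher by a log2 ratio of at least 2.91. The lowest log2 ratio of these genes was 3.02, and 2.98 once a trend with length or GC was removed. The average trend over protein-coding genes thus accounts for little of these ratios. Ratios so far above 2-fold could hardly have failed this check, so nothing further about length or GC is concluded. A candidate explanation is an osmotic response to the added sodium salt, but the other 6 measured genes known to respond to tonicity had a median of 0.18, at percentile 79.85 of random lists, with 0 past the rule, so this hypothesis stays open, and a control culture of equal osmolarity, which it needs, was not analysed here. An effect of inhibiting lactate dehydrogenase on these genes also stays open.

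Hepatocyte genes were lower in both steps, with medians of -0.73 and -0.72. Over 34 markers of blood, endothelial and stellate cells, the median in the oxamate library was 0 CPM. This pooled median would stay low if only 1 of these kinds were abundant. Taken singly, blood, endothelial and stellate markers had medians of 0, 0 and 0.34 CPM, with 10 of 12, 9 of 10 and 7 of 12 below 1. These medians argue against a large share of any of these cells in that library. LYZ, PECAM1 and LUM, the most abundant of each kind, had 60.0, 20.0 and 23.2 CPM, although Hep3B cells may express some of these genes themselves. Removing a trend with gene length or GC left a median of -0.66 in the step nearest 0 (counting interval from -0.72 to -0.58). Such a trend therefore does not account for the pattern as a whole. The other scalings left -0.58 (from -0.62 to -0.52). A scaling moves all genes by a common amount and cannot change the list's place among random lists. These values show only how far these scalings differ, and no conclusion on scaling is drawn from them. Low oxygen and oxamate may each lower hepatocyte genes, as a hypothesis found and tested on the same libraries, and the spread between cultures remains unmeasured.

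HIF targets were higher in hypoxia and higher again with oxamate, by a median of 0.66 (counting interval 0.63 to 0.72). A trend with length or GC is argued against by a lowest corrected median of 0.65 (0.63 to 0.73). Among 100 simulated unchanged libraries with an assumed coefficient of variation of 0.2, the highest median of the list was 0.28, but simulated spreads exclude nothing, and a chance position of the single hypoxia library cannot be told apart from an effect of oxamate without a second hypoxia library. Longer or deeper lack of oxygen in the culture with oxamate was not tested and could also raise these genes.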
